A study of Zea mays with 6 samples.

How the data were processed

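RNA was sequenced from maize (Zea mays) kernels at 13 days after pollination, 3 libraries of WT and 3 of the shrek1 mutant. Per the labels' protocols, the plants grew in a field under natural conditions, the pericarp was peeled off, total RNA was extracted with Trizol, and libraries were made with a directional (strand-keeping) Illumina kit. Whether the 3 replicates of a genotype came from separate plants or ears, and whether WT kernels were siblings of the mutant kernels, is not given in the sources used here, so a difference between lines or ears could be part of any difference between the genotypes.

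The deposited count table holds raw counts for 49785 genes, with 1 column per library and no normalization by the authors. The deposited FPKM table holds the same genes in fragments per kilobase of gene per sequencing depth unit. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used in processing, without a stated role, order or strand setting. The deposited FPKM values equalled the counts divided by the table's gene length and by 1 library size per library. Those library sizes were proportional to the size factors that DESeq2 computes from the counts, with a largest deviation of 9.05e-11%. The genome build is not given in the labels. Gene names and descriptions came from the deposited table, and maize symbols and chromosome numbers from the reference table of assembly Zm-B73-REFERENCE-NAM-5.0, in which 49738 of the 49785 gene identifiers were found and 48178 had the same start. Coordinates are those of the deposited table.

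The totals were 17145006 to 20288565 counts per library. A count of 0 allowed up to 3 counts per library, which is 0.142 to 0.185 CPM (counts scaled to library size) after scaling. Intervals and floors cover counting error only and leave out variation between libraries. The reads carry no molecular identifiers, so duplicate reads are counted separately and the intervals may be too narrow. For a gene at 0 in every library of a group, the fold is given as a lower bound against that floor of 3 counts per library. For a gene with 1 to 3 counts in a group, the ratio of normalised totals is given with its 95% counting interval.

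Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 22681 genes, and scaled with TMM factors, which were 1.055, 1.099 and 1.163 in WT and 0.918, 0.936 and 0.864 in shrek1. The groups were compared with edgeR's quasi-likelihood test (robust dispersion, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.149. "Rose" and "fell" are used of genes past that threshold. CPM values are TMM-normalised, and standard errors (SE) of log2 fold changes were derived from the fold change and the test's F value, so they are approximate.

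The test was checked on simulated counts drawn for the 22681 genes from the libraries' means and sizes, in 10 simulations with 200 changed genes each. It recovered 14.6% of genes changed by a log2 fold change of 0.5, 59.6% at 1, 90.2% at 2 and 92.6% at 3. Of 1425 calls in the simulations, 140 were false (9.82%), above the nominal 5% of the threshold. A first check with a single simulation gave a false share above 10%, after which the average over 10 simulations was used instead. Each simulation changed 200 of 22681 genes, where the real comparison called 64.4% of them. The simulated shares of recovered and false calls therefore need not hold for the real comparison.

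The comparison, its test, the rule for named genes and 24 gene lists were fixed before the data were examined. Lists were defined by symbols and by words in gene descriptions. They are zeins, starch synthesis, endosperm transcription factors, cytosolic ribosomal proteins, organellar ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, translation factors, basal endosperm transfer layer, embryo-surrounding region, aleurone, embryo, photosynthesis, flavonoid and lignin, cell cycle and DNA replication, histones, endoplasmic reticulum folding, cytosolic heat shock proteins, defence and protease inhibitors, oxidative stress and detoxification, auxin, sugar transport and invertase, programmed cell death and senescence, and the TCA cycle with mitochondrial electron transport. Matching by words let in some genes of another function. Cleaned lists, without some of these and without any gene not annotated as protein-coding, were added after an exploratory fit had been seen. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the 24 lists.

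Named genes are, first, the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with a mean of at least 10 CPM in the higher group, no overlap between groups and a named protein. Second, for each list, they are the 2 most abundant members past the threshold in each direction. This rule named 106 genes, of which 6 overlapped another annotated gene and 3 a tested one. Genes named outside the rule are marked as chosen after their values were seen. The targeted gene could not be matched to an identifier in the tables, so it is not reported and the genotype labels could not be checked with it.

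Shares of counts were compared with two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1. Called genes were tested in 219 windows of 10 Mb, with 431 windows of 5 Mb as an alternative, and in 340 domain families, from a column of the deposited table, with Fisher's exact test and Benjamini-Hochberg adjustment. A domain family needed at least 5 tested members. Fisher's test treats genes as independent, so its p-values can be too small where genes change together.

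Alternatives were other scalings (DESeq2's median-ratio method, upper quartile, library size only, scaling without zeins), other filters (none, or at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited FPKM with 1 or 0.1 added, the replicate number as a block, each library left out in turn, a test against a log2 fold change of 0.5 and an offset for gene length. The offset was a smooth curve of the log2 fold changes of all tested genes on gene length, fitted within 5 bins of expression to these same data. Random lists matched on expression, or on expression and gene length, were drawn 10000 times. Annotation and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. GC content was not analysed here.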

Results

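RNA was sequenced from peeled maize kernels at 13 days after pollination, in 3 libraries of WT and 3 of the shrek1 mutant. The libraries held 17145006 to 20288565 counts over 49785 genes, of which 16047 had no count in any library. Across genes, the log2 CPM of library pairs had Pearson correlations of 0.974 to 0.985 in the 6 pairs within a genotype and 0.813 to 0.829 in the 9 pairs between genotypes, where genes are not independent replicates. The first principal component separated the genotypes and held 87.4% of the variance. The second held 4.09% and set shrek1 replicate 3, at -47.0, apart from the other shrek1 libraries, at 15.4 and 29.2.

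The comparison asked how the mRNA of shrek1 kernels differed from that of WT kernels at this stage. The targeted gene could not be matched to an identifier in the tables, so the genotype labels could not be checked with it. As a share of all counts, the shrek1 kernels held more mRNA of the translation machinery and less of the zein storage proteins and of embryo genes. These values are relative and give no amount of mRNA per kernel. Of 330 tested cytosolic ribosomal protein genes, 296 rose and 12 fell, and their share of all counts was 4.21% ± 0.553 (SD, n = 3) in WT and 13.0% ± 0.487 in shrek1. Of 43 tested members of the zein list, 39 fell and 4 did not pass the test, and their share was 17.2% ± 1.99 in WT and 5.57% ± 0.785 in shrek1. Of 47 tested embryo genes, 35 fell and 6 rose, and their share was 1.56% ± 0.174 in WT and 0.142% ± 0.0202 in shrek1. Each of these shares separated the genotypes in all 6 libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and 0.104 after Benjamini-Hochberg adjustment.

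By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14609 of 22681 tested genes passed (64.4%), 7264 higher and 7345 lower in shrek1. At least 2-fold changes numbered 7748, of which 3213 were higher and 4535 lower, and at least 4-fold changes 3158, of which 861 were higher and 2297 lower. The unadjusted p was under 0.05 for 15334 genes, and the CPM of the genotypes did not overlap for 15871 genes, where chance gives 10% of genes. Higher genes made up 49.7% of the called genes and 41.5% of those called at 2-fold. With library size as the only scaling, these shares were 34.03% and 26.4%, and an offset for gene length put the second at 53.9%.

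**Figure D1:**
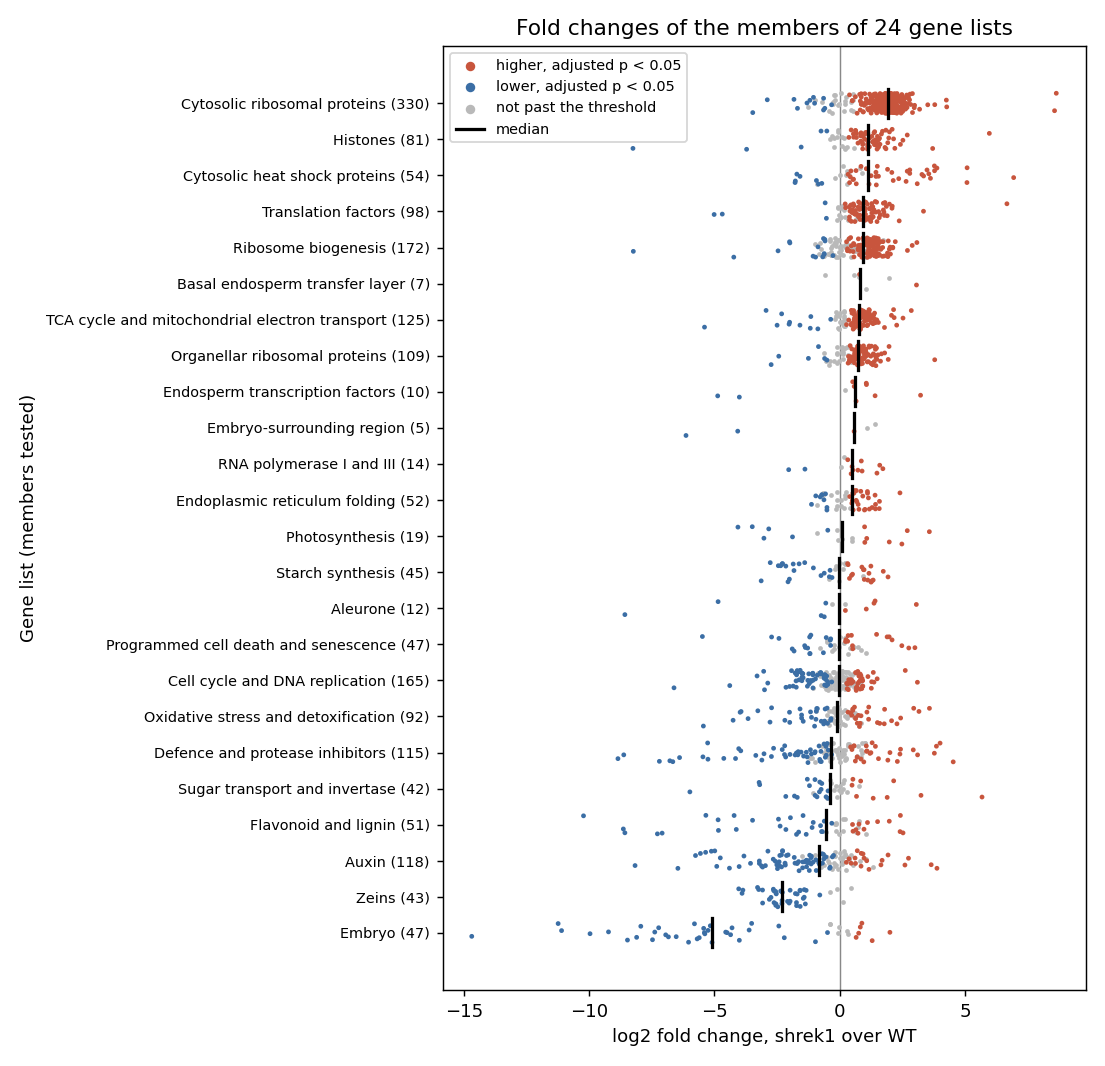
Log2 fold change (shrek1 over WT, horizontal axis) of every tested member of the 24 gene lists, with the number of members in brackets and a bar at each median. Points are coloured by edgeR's adjusted p; the medians run from -5.09 for the embryo list to 1.92 for cytosolic ribosomal proteins.

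Cytosolic ribosomal protein genes encode the structural proteins of the ribosome, and their median log2 fold change was 1.92. The 60S acidic protein P0 gene (LOC542454, chromosome 6) rose from 467 ± 58.1 to 1791 ± 156 CPM (SD, n = 3 each), and the 40S protein S4 gene (LOC103644306, chromosome 1) rose from 354 ± 31.1 to 1687 ± 142 CPM. A pair of genes for ubiquitin fused to 60S protein L40 had larger changes. LOC103633191 (chromosome 7, 159193995 to 159196649) rose from 1.07 ± 0.176 to 411 ± 74.9 CPM, and LOC100284418 (chromosome 2, 204440608 to 204441490) from 0.0786 ± 0.136 to 36.5 ± 7.43 CPM. Among the members that fell, a 40S S6 gene (LOC109939511) had a log2 fold change of -1.30 ± 0.15 (SE) and a 40S S10 gene (LOC103653164) of -0.32 ± 0.09. The list differed from other genes by limma's camera with adjusted p = 3.44e-73 at the preset correlation, and adjusted p = 0.156 with an estimated correlation. With the offset for gene length the list's median was 1.01, and 282 members were higher. In the cleaned list, 5 genes were lower.

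Translation factors shifted the same way, with 81 of 98 members higher, 4 lower and a median log2 fold change of 0.95. The elongation factor 1-alpha gene LOC100284707 (chromosome 7, 166654624 to 166657363), whose protein brings aminoacyl-tRNA to the ribosome, rose from 41.4 ± 5.82 to 4243 ± 364 CPM (n = 3 each). A second elongation factor 1-alpha gene, LOC542581, rose from 930 ± 50.4 to 2296 ± 21.0 CPM. The most abundant lower members, LOC118476815 and LOC100216986, carry descriptions of a transcription elongation factor and of a chloride-proton antiporter. With library size only, 8 members were lower, and 9 with the offset for gene length. For this list camera gave adjusted p = 1.1e-17, and adjusted p = 0.156 with an estimated correlation.

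Ribosome biogenesis genes, which encode nucleolar factors that process pre-rRNA, had 111 of 172 members higher and 15 lower (24 and 26 by limma-trend on FPKM plus 1 and plus 0.1), with a median of 0.94. Nucleolin 2 (LOC100194303) rose from 481 ± 21.8 to 1108 ± 13.9 CPM, and a nucleolar GTP-binding protein gene (LOC100273647) from 181 ± 5.36 to 347 ± 12.9 CPM. A second nucleolin gene (LOC103654496) fell by 0.67 ± 0.14 (SE) on the log2 scale. In the RNA polymerase I and III list, 10 of 14 members rose and 2 fell, with RNA polymerase I subunit 1 (LOC100279825) at a log2 fold change of 0.50 ± 0.09 and a repressor of RNA polymerase III transcription (LOC103627379) at -1.38 ± 0.17. With library size as the only scaling, 6 polymerase members were higher and LOC100279825, at 0.21, did not pass. Organellar ribosomal protein genes had 79 of 109 members higher, 6 lower (11 with library size only, 13 with the offset for gene length) and a median of 0.73, among them a 30S S5 gene (LOC100281473) at 0.97 ± 0.09. By camera, adjusted p was 1.03e-13 for ribosome biogenesis, 0.0215 for the polymerases and 6.99e-09 for organellar ribosomal proteins. These became adjusted p = 0.156, adjusted p = 0.444 and adjusted p = 0.156 with an estimated correlation.

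**Figure D2:**
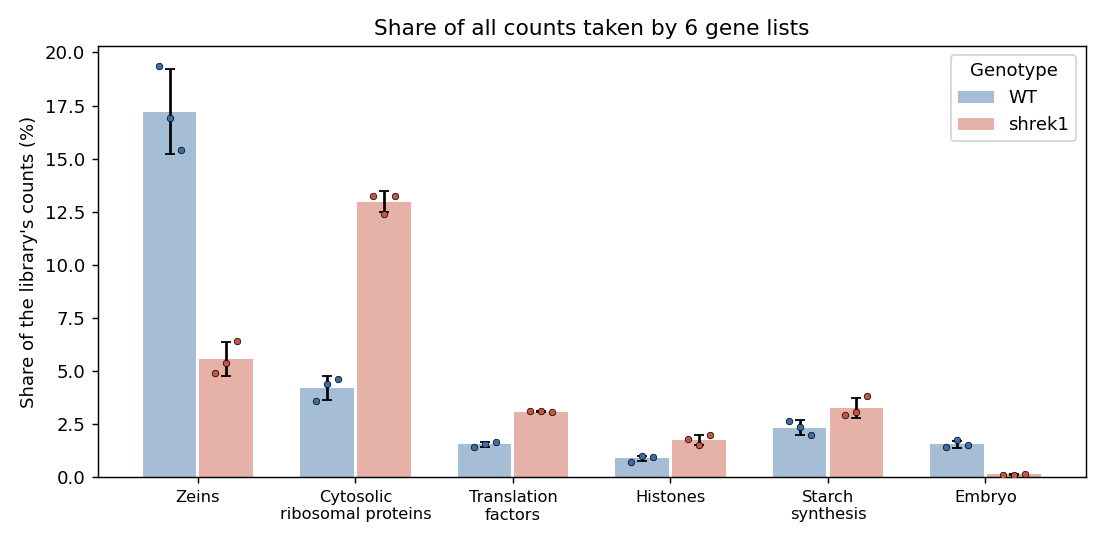
Share of each library's counts (percent, vertical axis) taken by 6 gene lists, with bars at the mean of 3 libraries, error bars of 1 SD and a point per library. The mean share of zeins was 17.2% in WT and 5.57% in shrek1, and that of cytosolic ribosomal proteins 4.21% and 13.0%.

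Zeins are the storage proteins of the endosperm, and their list had a median log2 fold change of -2.28. The list also holds zein pseudogenes and a gene for a protein-body membrane protein, which did not pass. In the cleaned list, without genes not annotated as protein-coding, 27 of 30 members were lower. The beta zein gene bz15 (chromosome 6, 52387414 to 52388136) fell from 31841 ± 2716 to 12348 ± 3036 CPM (SD, n = 3 each), and the 16 kDa gamma zein gene gz16 (chromosome 2, 188382021 to 188382858) from 21584 ± 4600 to 8559 ± 2287 CPM. Neither passed with limma-trend on log2 of FPKM plus 1, at log2 fold changes of -1.42 and -1.37. The most abundant zein gene, gz27, did not pass by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at 37049 ± 4609 and 28234 ± 2655 CPM (adjusted p = 0.055). The alpha zein gene z1C2 fell by 3.07 ± 0.21 (SE) on the log2 scale, and it and gz27 were chosen after their values were seen. The list had camera adjusted p = 5.64e-11, and adjusted p = 0.402 with an estimated correlation.

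Starch synthesis genes went both ways, with 17 of 45 members higher, 19 lower and a median of -0.01. The sucrose synthase gene sh1 (LOC542365, chromosome 9), which supplies starch synthesis in endosperm, rose from 7295 ± 1618 to 17342 ± 3948 CPM, and the sucrose synthase gene sus1 (LOC542247) fell from 809 ± 152 to 229 ± 20.8 CPM. The ADP-glucose pyrophosphorylase gene sh2 (LOC542761) rose by a log2 fold change of 0.47 ± 0.16, and the granule-bound starch synthase gene waxy1 (LOC541854) fell by 0.74 ± 0.28. Chosen after their values were seen, the endosperm starch genes bt1 (LOC732804), ae1 (LOC542238) and bt2 (LOC541902) rose by 1.34 ± 0.18, 1.17 ± 0.14 and 1.12 ± 0.19. The call of sh2 was lost with library size as the only scaling (0.19) or the offset for gene length (0.21), and that of waxy1 without WT replicate 1 (-0.62), among other settings. With library size only, 11 starch genes were higher and 23 lower. The list as a whole had camera adjusted p = 0.243.

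Of 10 endosperm transcription factor genes, 7 rose and 2 fell (1 by limma-trend on genes with a mean FPKM of at least 1). The zein regulator opaque2 (LOC542375) rose from 125 ± 26.7 to 263 ± 38.6 CPM and naked endosperm1 (LOC542199), a regulator of aleurone fate, from 180 ± 24.9 to 377 ± 72.4 CPM. Viviparous1 (LOC542523), a regulator of seed maturation, fell from 107 ± 18.2 to 6.67 ± 1.46 CPM. The list shared 2 tested members with the aleurone list and 1, viviparous1, with the embryo list, where most members fell. The list's median was 0.62 but its mean -0.01, and camera gave adjusted p = 0.243.

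Embryo genes had a median log2 fold change of -5.09. The oil body gene ole1 (LOC542263, chromosome 2, 22219327 to 22220208) fell from 3886 ± 550 to 92.3 ± 8.91 CPM (SD, n = 3 each), and a vicilin-like storage protein gene (LOC103639475, chromosome 9) from 2430 ± 311 to 43.8 ± 5.94 CPM. The storage globulin gene glb2 (LOC542382, chromosome 1, 293871724 to 293873694) had 179 ± 33.3 CPM in WT and no count in shrek1, at least 1010-fold lower. A late embryogenesis abundant gene (LOC100286284) had 1 count over the shrek1 libraries, and its WT to shrek1 ratio was 3290 with a 95% counting interval of 590 to 130000. Among the members that rose were a group 2 late embryogenesis abundant gene (LOC100191528), at 0.83 ± 0.19 (SE) and, without a call, 0.34 with the offset for gene length, and a caleosin gene (LOC100285543), at 0.76 ± 0.12. Camera gave adjusted p = 4.01e-32, and adjusted p = 0.156 with an estimated correlation.

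**Figure D3:**
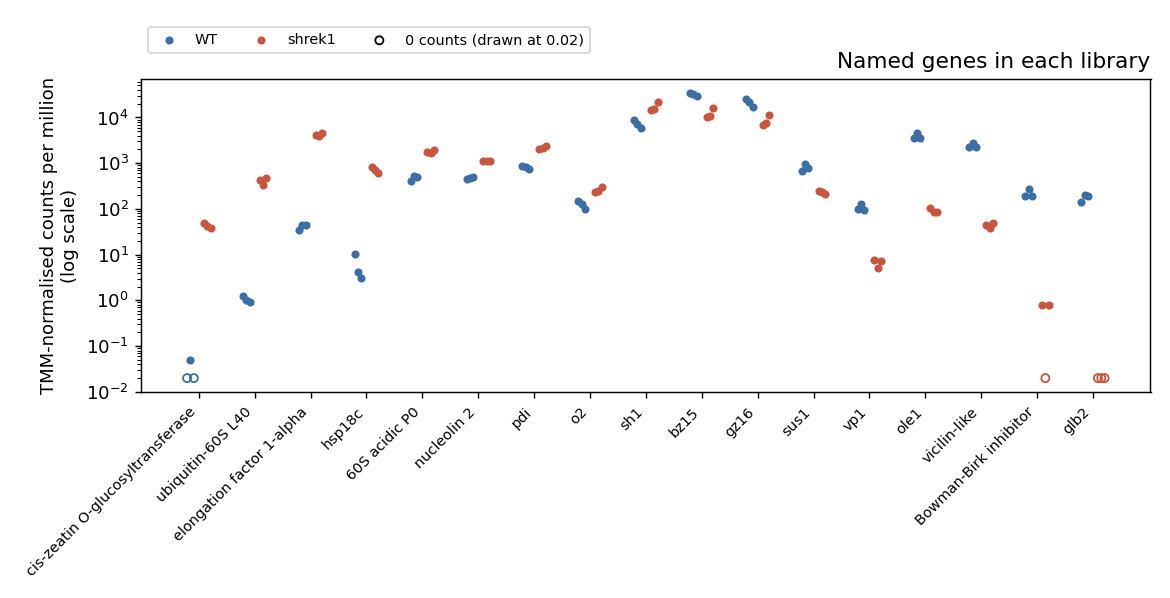
TMM-normalised CPM (log axis) of 17 named genes in each library, with 1 point per library and open circles, drawn at 0.02 CPM, for libraries with no count. Elongation factor 1-alpha stood at a mean of 41.4 CPM in WT and 4243 in shrek1, and ole1 at 3886 and 92.3.

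Lists for cell types of the endosperm were small. In the basal endosperm transfer layer list, 2 of 7 members rose, a MATERNALLY EXPRESSED GENE-like gene (LOC100382777) by a log2 fold change of 0.80 ± 0.10 and betl2 (LOC542570) by 3.07 ± 0.79, the latter from 1.32 ± 0.423 to 11.1 ± 9.45 CPM. With the offset for gene length LOC100382777, at 0.25, did not pass, and without shrek1 replicate 3, 8 of 10 tested members were higher and 1 lower. Without a filter 5 of 24 tested members were higher, and with DESeq2 7 of 17. In the aleurone list, 5 of 12 members rose and 5 fell (3 by limma-trend on genes with a mean FPKM of at least 1). Pale aleurone color 1 (LOC100285351), a regulator of anthocyanin pigment, rose by 3.06 ± 0.11 and defective kernel 1 (LOC542509), needed for aleurone cell fate, fell by 0.55 ± 0.10. In the embryo-surrounding region list, the 3 members past the threshold share wording with the list: the ethylene-responsive factor genes LOC100281327 (0.58 ± 0.11, and 0.15 without a call with the offset for gene length) and LOC100280953 (-6.13 ± 0.37), and the peptide gene CLE25 (LOC103644198, -4.07 ± 0.82). Camera gave adjusted p = 0.542, 0.558 and 0.415 for these lists, with medians of 0.80, -0.03 and 0.58. The test's direction was opposite to the median's sign for the aleurone and the embryo-surrounding region.

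Histone genes had 62 of 81 members higher, 5 lower and a median of 1.12. A histone H2A gene (LOC103639303) rose from 674 ± 103 to 1827 ± 345 CPM, and a histone H1 gene (LOC103638138) fell from 85.7 ± 17.5 to 29.6 ± 2.71 CPM. In the cell cycle and DNA replication list, 42 of 165 members rose and 52 fell, with a median of -0.04; a gene for CDC20, an activator of the anaphase-promoting complex (LOC100384140) fell by 0.77 ± 0.09 on the log2 scale. Camera gave adjusted p = 1.57e-09 for histones, with adjusted p = 0.503 with an estimated correlation, and 0.546 for the cell cycle. With library size as the only scaling, 23 cell cycle genes were higher and 74 lower, with a median of -0.33, and 10 histone genes were lower. By limma-trend on genes with a mean FPKM of at least 1, 3 histone genes were lower. With the offset for gene length, 31 histone genes were higher, 14 were lower, their median was 0.17 and LOC103639303, at 0.38, did not pass.

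Chaperone genes were mostly higher. Of 54 cytosolic heat shock protein genes, 37 rose and 7 fell, with a median of 1.12; hsp18c (LOC100037778, chromosome 8, 22215123 to 22216017), a small heat shock protein, rose from 5.95 ± 3.999 to 725 ± 118 CPM and an HSP70 gene (LOC100501536) from 87.9 ± 5.74 to 754 ± 181 CPM. Of 52 endoplasmic reticulum folding genes, 28 rose and 9 fell, with a median of 0.50. The cleaned list, which dropped genes not annotated as protein-coding, had 28 of 46 members higher and 5 lower. It kept members that match by wording only, such as LOC103632614 and LOC103647378, described as proton pump-interactor BIP103, which both rose. Protein disulfide isomerase (LOC606409) rose from 815 ± 57.4 to 2197 ± 206 CPM. Respiration genes had 92 of 125 members higher and 11 lower, with a median of 0.79; the mitochondrial malate dehydrogenase gene mdh2 (LOC100274264) rose by 1.19 ± 0.11 and the beta subunit of ATP synthase (LOC542267) by 0.77 ± 0.10. Camera gave adjusted p = 1.01e-05, 0.00813 and 4.16e-10 for these lists, and adjusted p = 0.473, adjusted p = 0.261 and adjusted p = 0.156 with an estimated correlation. With library size only, 17 respiration genes were lower. With the offset for gene length, 52 respiration genes were higher and 31 lower, with a median of 0.11.

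Auxin genes were lower in 67 of 118 members and higher in 19, with a median of -0.81. An auxin response factor gene (LOC100285977) fell by 0.37 ± 0.08 on the log2 scale and another (LOC103630727) rose by 0.62 ± 0.09. Flavonoid and lignin genes were lower in 26 of 51 members and higher in 12 (7 with library size only), with a median of -0.56, and the lignin gene cad1 (LOC100191885) fell from 78.3 ± 10.2 to 1.90 ± 1.498 CPM. Auxin and flavonoid genes had camera adjusted p = 2.6e-05 and 0.0188, and adjusted p = 0.156 and adjusted p = 0.473 with an estimated correlation.

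The remaining lists went both ways and did not pass camera. Of 115 defence and protease inhibitor genes, 28 rose and 48 fell, with a median of -0.34 and adjusted p = 0.201. A Bowman-Birk trypsin inhibitor gene (LOC100274196) fell from 217 ± 42.7 to 0.537 ± 0.465 CPM and a defensin gene (LOC100280590) rose from 133 ± 14.8 to 705 ± 169 CPM. Of 42 sugar transport and invertase genes, 9 rose (5 with library size only) and 18 fell, with a median of -0.36 and adjusted p = 0.284; a SWEET sugar transporter gene (LOC100282648) rose by 2.16 ± 0.14 and another (LOC100273706) fell by 0.74 ± 0.12. Of 92 oxidative stress genes, 26 rose and 30 fell, with a median of -0.10 and adjusted p = 0.798, and catalase 1 (LOC542369) fell by 0.36 ± 0.08. Of 47 cell death and senescence genes, 14 rose (7 with library size only, 9 with upper-quartile scaling) and 17 fell, with a median of -0.03 and adjusted p = 0.546, and a senescence-associated gene (LOC100191434) fell by 1.39 ± 0.15. Of 19 photosynthesis genes, 7 rose and 6 fell (10 by limma-trend on FPKM plus 0.1), with a median of 0.09, a mean of -0.10 and adjusted p = 0.843. A plastocyanin gene (LOC100281113) rose by 1.08 ± 0.11, but stood at -0.84 with the offset for gene length, and a light-harvesting-like gene (LOC100285503) fell by 2.83 ± 0.18.

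Adjusted over the list alone, 40 zeins were lower, 298 cytosolic ribosomal protein genes were higher and 14 lower, and 16 ribosome biogenesis genes were lower. On the same basis 51 cell cycle genes were lower, 63 histone and 29 endoplasmic reticulum folding genes were higher, 50 defence genes were lower and 95 respiration genes were higher. The other counts were the same as over all genes.

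The largest increases among the named genes were of a cis-zeatin O-glucosyltransferase gene and a sulfotransferase gene. The first, LOC100273251 (chromosome 2, 20057577 to 20059096), an enzyme that conjugates a cytokinin, had 1 count over the WT libraries and 43.7 ± 5.74 CPM in shrek1, a ratio of 2590 with a 95% counting interval of 464 to 102000. The second, LOC100280082 (chromosome 7, 173668043 to 173669314), rose from 0.198 ± 0.166 to 207 ± 16.3 CPM. A MYB transcription factor gene (LOC100384300) had a ratio of 378 with an interval of 104 to 3130, and a lipocalin gene (LOC100272963) of 303 with an interval of 103 to 1470. Besides glb2, genes with no count in shrek1 included a glutamate receptor 3.5 gene (LOC100383810, chromosome 7), at least 122-fold lower, and protodermal factor 1 (LOC100382457, chromosome 3), known from epidermis, at least 112-fold lower. A potassium transporter gene (LOC103645946, chromosome 2) was at least 84.4-fold lower.

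Genes with at most 3 counts in all libraries of a genotype and a mean of at least 10 CPM in the other numbered 4 for shrek1 and 32 for WT. The 4 were LOC100273251, LOC100384300, LOC100272963 and LOC103635836. The 32 included WUSCHEL-related homeobox 6 (LOC103634590) and, on chromosome 4, the benzoxazinoid defence genes LOC103652724 and LOC103652726, all chosen after their values were seen. By Fisher's exact test over 219 windows of 10 Mb, no window held an excess of these genes, with a smallest adjusted p of 0.228. Called genes of either direction were depleted in 1 window, chromosome 6 from 20000001 to 30000000, with 15 of 54 tested genes (adjusted p = 1.44e-05), and genes at least 2-fold lower were enriched at the start of chromosome 4, up to 10000000, with 51 of 154 (adjusted p = 0.024). With windows of 5 Mb no window of the 2-fold lower genes passed, with a smallest adjusted p of 0.105, and 2-fold higher genes were enriched in 1, chromosome 1 from 195000001 to 200000000, with 21 of 62 (adjusted p = 0.0317), a call not made at 10 Mb.

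Zeins, histones, ribosomal proteins, L40 fusions and elongation factor 1-alpha form families of near-identical copies, so the values of their single members are uncertain where reads are shared. The strand setting of the counting is not given in the sources used here, so the values of antisense and overlapping genes are uncertain.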

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

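The cleaned lists, the gene length offset applied to lists and named genes, and the families under other scalings and that offset were chosen after the data had been seen. The other alternatives were fixed before the data were examined. The number of called genes stayed between 12741 and 15409 over the other scalings, filters, units and tests, apart from the stricter test below, and between 13516 and 14506 with a library left out; with the replicate number as a block it was 14348, although deviations did not pair by number (correlations of 0.096, -0.049 and 0.028). With a library left out, 1089 to 1483 of the 14609 calls were lost. The gene length offset lost 3624 and called 129 in the opposite direction. The median log2 fold change of all genes was -0.01, and -0.15 with upper-quartile scaling, -0.30 with library size only and 0.11 with the gene length offset. Of the named genes' values, 1221 kept their side of the threshold under other settings, 47 lost it, and 1 reversed: LOC100283267, a BAX inhibitor-like gene, went from 0.24 to -0.0517 with library size only, by that scaling's shift of all genes. With a library left out, 603 kept it and 33 lost it. With the gene length offset 83 kept it, 13 lost it and 10 reversed: LOC100273480 (-0.63), LOC100281113 (-0.84), LOC107282093 (-0.0455), LOC100193413 (-0.75), LOC100284475 (-0.17), LOC542764 (-0.19), LOC100283339 (-0.51), LOC103633920 (0.11), LOC100283267 (-0.37) and LOC100283057 (-0.35), as the offset removes the trend with gene length. Reversed means a change of sign at any p. LOC107282093, LOC100284475, LOC542764 and LOC103633920 did not pass the threshold with the offset. Under the settings fixed before the data were examined, list medians moved by at least their spread between libraries of a genotype in 86 cases and by less in 202. When a library was left out, such moves numbered 29, and 115 medians stayed within that spread. Depth limits the genes near the floor of 3 counts. Where no reason is given, the cause was not tested.

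The stricter test against a log2 fold change of 0.5 called 9562 genes, 4481 of them higher. With limma-trend on log2 of FPKM plus 1, genes changed at least 2-fold numbered 4907, of which 2609 were lower, since the added 1 shrinks folds of low values. With a mean FPKM of at least 1 as well, these numbers were 4626 and 2371, where only 19223 genes were tested. With library size only, 2112 genes were at least 2-fold higher. At 2-fold, 0 windows of called genes passed, against 1, and 7 families of higher genes, 5 of them enriched, against 24, 10 of them enriched.

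With library size only, higher members numbered 11 for starch synthesis, 6 for RNA polymerases, 7 for flavonoid and lignin, 23 for the cell cycle, 5 for sugar transport and 7 for cell death. Lower members numbered 11 for organellar ribosomal proteins, 8 for translation factors, 10 for histones and 17 for respiration. Upper-quartile scaling left 9 cell death genes higher. With FPKM plus 1, 24 ribosome biogenesis genes were lower; with FPKM plus 0.1, 26, and 10 photosynthesis genes were lower. With a mean FPKM of at least 1, lower members numbered 1 for endosperm transcription factors, 1 for the embryo-surrounding region, 3 for aleurone and 3 for histones; at 1 CPM in 3 libraries, 1 embryo-surrounding region gene was lower. Fewer genes were tested under both. Limma-voom called 1 member of the zein list higher. Higher members of the basal endosperm transfer layer numbered 5 without a filter and 7 with DESeq2. With a library left out they numbered 2 to 8, lower members of that list 0 to 1, higher members of the zein list 0 to 1 and higher embryo-surrounding region genes 1 to 2. The upper ends came without shrek1 replicate 3, and for zeins without WT replicate 1.

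The cleaned lists had 5 cytosolic ribosomal protein genes lower, 0 embryo-surrounding region genes higher and 0 lower, and 5 endoplasmic reticulum folding genes lower, because members were removed. With the gene length offset, lower members numbered 13 for organellar ribosomal proteins, 9 for translation factors, 14 for histones and 31 for respiration. Higher members numbered 31 for histones, 52 for respiration, 1 for the basal endosperm transfer layer and 0 for the embryo-surrounding region.

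With an estimated correlation, camera's adjusted p was 0.156 for cytosolic and organellar ribosomal proteins, ribosome biogenesis, translation factors, embryo, auxin and respiration, 0.402 for zeins, 0.444 for RNA polymerases, 0.473 for flavonoid and lignin and for heat shock proteins, 0.503 for histones and 0.261 for endoplasmic reticulum folding. Fry tests a list's members against no change, not against other genes. Its adjusted p was 0.00707 for endosperm transcription factors, with direction higher. With direction lower it was 0.0152 for starch synthesis, 0.00852 for the embryo-surrounding region, 0.00686 for defence and 0.00307 for sugar transport. For the embryo-surrounding region that direction was opposite to the median of 0.58. With 64.4% of all tested genes called, such a pass does not set a list apart from other genes.

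As a share of summed FPKM, the difference (shrek1 minus WT, percentage points) was -19.5 for zeins, 14.2 for cytosolic ribosomal proteins, -1.66 for embryo and -13.8 for the 10 most abundant genes, against -11.7, 8.76, -1.42 and -6.06 of counts, since FPKM weights short genes more. Of the counts outside zeins it was -1.74 for embryo and 0.0272 for the top 10. Of all counts, the 50 most abundant genes differed by -7.63.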

Other observations

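The patterns weighed below were noticed in an exploratory fit before their tests were written. The tests' bounds were set before the values they measure were seen, except as stated below for the ribosomal protein genes. The use of the SD across the embryo identity genes as their spread and the check of families under other scalings were chosen after those values had been seen. Domain families of the deposited table described further groups. By Fisher's exact test with Benjamini-Hochberg adjustment over 340 families, 24 families passed for genes higher in shrek1, 10 of them enriched and the rest depleted, and 42 for genes lower, 30 of them enriched. Fisher's test treats genes as independent, and genes of the same libraries can change together, so these p-values can be far too small. For the gene lists, camera with an estimated correlation gave adjusted p of 0.156 or more. No such correlation was estimated for the families. Higher genes were enriched among elongation factor type GTPases (30 of 37, adjusted p = 9.28e-08), LSM RNA-binding proteins (26 of 31, 2.07e-07), DEAD-box RNA helicases (41 of 73, 0.000882), RRM RNA-binding proteins (125 of 241, 1.74e-08) and proteasome subunits (23 of 36, 0.00286). HSP70 proteins were higher in 22 of 31 genes (0.000688) and RNase PH subunits of the exosome in 9 of 11 (0.0197).

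Lower genes were enriched in several families of transcription factors and other proteins, with the same limit on their p-values. All 14 tested zinc finger homeodomain genes (adjusted p = 1.18e-05) and all 8 YABBY genes (0.00293) were lower by Fisher's exact test on edgeR's calls, as were 7 of 8 KNOX genes (0.0242), 22 of 31 START domain genes (0.000742), 21 of 32 Dof genes (0.00351), 23 of 39 GRAS genes (0.0114) and 24 of 34 genes with an auxin response factor domain (0.000352). Kinesins, the motors of microtubules, were lower in 42 of 59 genes (1.39e-07), cytochrome P450 enzymes in 57 of 116 (0.00373) and protein kinases in 293 of 602 (1.76e-14). The KNOX genes include kn1, an embryo identity gene at -3.61, and a smaller share of embryo, weighed below, stays open for the lower families and for the lower auxin and flavonoid genes, for which it was not tested. The median of each family named so far kept its sign under the 4 other scalings and the gene length offset, but several came close to 0. The offset moved the median log2 fold change of proteasome genes from 0.733 to 0.0593, of LSM genes from 0.791 to 0.264, of P450 genes from -0.667 to -0.178 and of protein kinases from -0.453 to -0.149. That of RRM genes went from 0.315 to 0.106, and to 0.026 with library size only. The NB-ARC family, also enriched among lower genes, changed sign with the offset, from a median of -0.586 with 31 of 61 genes lower and 5 higher to 0.228 with 10 lower and 19 higher. The offset left 44 P450 genes lower and 40 higher, 27 kinesin genes lower, and 14 LSM, 14 proteasome and 76 RRM genes higher, and with library size only 78 RRM genes were higher and 78 lower.

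Cytosolic ribosomal protein genes were higher in shrek1, with a median log2 fold change of 1.92. A lower zein share alone could raise other genes, but by nearly the same amount for each. With zeins left out of the scaling, the list's median stood 1.93 above that of all genes. Of 10000 lists matched on expression, 95% lay between 0.349 and 0.547. A scaling shifts all genes nearly alike, so leaving zeins out could not change this difference. It was set by the pattern noticed in the exploratory fit. Short genes were higher as a class, with a median of 0.36 in the shortest of 4 equal classes of length and -0.23 in the longest. Without the list's own genes these medians were 0.30 and -0.23. Yet the list's 1.92 lay above the 0.628 to 0.803 of lists matched on expression and gene length. The comparison without zeins is therefore no independent test, although a shift shared by all genes cannot set a list apart from them. The lists matched on length argue against gene length as the whole of the pattern, while gene length may account for part of it. Its offset left a median of 1.01, but was fitted to these same fold changes, the list's own included. The offset may thus remove part of the list's own change, so it cannot tell how large the part due to length is. Reads shared between paralogs stay open, and no biological explanation was tested.

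Embryo genes were lower in shrek1, which could reflect a smaller share of embryo in the kernel or a delay of late storage genes. A smaller share predicts that embryo identity genes fall too, with a median below -2, and a delay that they stay above -1. Of 6 identity genes, 4 were tested, and their median was -3.02 with an SD of 2.36 across genes: lec1 (LOC542498) at -4.49, kn1 (LOC542391) at -3.61, wox9c (LOC103630735) at -2.43 and wox2a (LOC103651027) at 0.89. The median lies below -2 by less than that SD, which measures how the genes differ and not the uncertainty of their median. Medians with 1 gene left out, the spread first used, ran from -3.61 to -2.43, all below -2. By that spread the prediction of a smaller share was met and that of a delay was not. Lec1, wox9c and kn1 each fell, from 87, 108 and 273 counts over the WT libraries to 3, 17 and 19 over the shrek1 libraries. Such low counts leave the size of these falls imprecise, but not their direction. However, wox2a, whose description is WUSCHEL-related homeobox 5, rose. The explanations therefore cannot be told apart with 4 genes. The kernels' tissues were not separated, so a change within the embryo stays open.

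Genes found in a single genotype could mark a chromosome segment of another line carried with the mutant allele. The 10 Mb windows that passed Fisher's test held 0% of these 36 genes, which argues against 1 segment as the source of most of them. With windows of 5 Mb, 3 of the 32 genes of WT fell in the first 5000000 bases of chromosome 4 (adjusted p = 0.0499). A smaller share of embryo, weighed above, stays open for the WT genes.

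The 6 libraries can be split into groups of 3 in 10 ways. The real split gave 14609 called genes and 1 of the 10 splits, the real one, gave as many. The highest of the other splits gave 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 197 genes at an unadjusted p under 0.05, and 0 by limma-voom. Each other split mixed the genotypes within both groups, which put the genotype difference into the spread of each group. Their low counts follow from the size of that difference, so they give no baseline for chance. With 10 splits no share can fall under 0.05.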
